A study of Homo sapiens with 30 samples.

How the data were processed

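RNA sequencing measured gene expression in HT29 cells, an established human colorectal adenocarcinoma line, after 24 h with vehicle or with a 70% ethanol extract of a traditional herbal formula. The 30 libraries fell into 13 groups: vehicle (n = 3), and high, medium and low doses (500, 100 and 20 µg/mL) of Soshiho-tang (n = 3 per dose), Yijin-tang (n = 3 per dose), Okbyeongpung-san (n = 2 per dose) and Soyo-san (1 library per dose). Groups, doses and replicate numbers came from the sample labels. The labels gave the vehicle as 0.1% DMSO and the design text as 2% DMSO, so the solvent content is uncertain. By the design text an extract with an IC20 under 500 µg/mL was used at its IC20 and at dilutions of that. The labels give 500, 100 and 20 µg/mL for every extract, and these label doses are used here, so the doses are uncertain. The design text also named wortmannin at 10 µM as a positive control, which is not analysed here. Per the labels' protocols, RNA had an integrity number above 7, and a directional library kit was used with 100 bp paired-end reads. The names of the vehicle libraries put them in a set apart from those of the extract libraries. Sample titles place Soyo-san and replicate 3 of Okbyeongpung-san in batch D and all other libraries in batch E, with no word on what a batch is.

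The deposited table held RSEM expected counts per gene, not normalised between libraries, with between 9.5% and 11.5% of a library's values not whole. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 were used with the human genome build GRCh38. The annotation release was not given in the sources used here. The table had 60675 rows of Ensembl gene identifiers, each naming a gene, and 30 named columns. A further 30 columns had no name and no values and were not used. Symbols were found for 56558 identifiers, and 57055 were found in GENCODE release 29, from which coordinates on GRCh38 were taken. Expected counts are estimates that divide reads between genes sharing sequence, so paralogs, pseudogenes, overlapping loci and readthrough transcripts are less certain than other genes.

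Expected counts were rounded to whole numbers. Library totals lay between 18.5 M and 36.2 M counts, with a median of 24.2 M. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, libraries were scaled by TMM, whose factors lay between 0.94 and 1.02, and groups were compared with the quasi-likelihood F-test with robust dispersions. Vehicle, Soshiho-tang and Yijin-tang (21 libraries, 15882 genes) shared a fit, and so did vehicle and Okbyeongpung-san (9 libraries, 15762 genes). The biological coefficient of variation was 4.7% and 7% in these fits. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, and a gene is called changed at an adjusted p below 0.05. Log2 fold changes are given with a standard error (SE) derived from the F statistic. Expression is given as counts per M (CPM) with the SD between libraries. Adjusted p-values of single genes in all parts are from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates within a group agreed to within sampling noise: chi-square per degree of freedom lay between 2.41 and 20.6.

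The groups, comparisons, tests, 35 gene lists with 717 genes, the rule for named genes and most alternatives were fixed before the data were examined. Of the list genes, 714 were found, and the 30 lists with at least 5 measured genes were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and again with the correlation estimated for each list. List p-values were adjusted over the 30 lists of a comparison. Members past the test were also counted with p-values adjusted over the list alone.

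Genes were named by rule. For each formula at 500 µg/mL against vehicle these were the 10 largest rises and 10 largest falls past the test with a mean of at least 2 CPM, with all libraries of both groups separated and an approved-style symbol. For other comparisons 5 and 5 were taken by the same rule, of which the 3 largest of each are named at 100 and 20 µg/mL. Up to 4 members with the smallest adjusted p per described list were added, from which the text takes examples. The rule also fixed 10 markers: CYP1A1, HMOX1, NQO1, CDKN1A, MKI67, HMGCS1, DDIT3, CXCL8, MUC2 and AXIN2. For Soyo-san, with 1 library per dose, there was no test. Log2 CPM values with a prior count of 2 were compared with the mean of the vehicle libraries, and genes with at least 5 CPM and the largest differences were named. The median of each list was placed among 10000 random lists of equal size matched on expression.

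The test was tried on simulated data with 200 genes changed by known amounts, 50 at each fold. In the comparison of Soshiho-tang at 500 µg/mL with vehicle, over 15882 genes, 48%, 68%, 86% and 92% of genes changed by 1.25, 1.5, 2 and 4-fold were recovered, with 10 false calls among 157 calls. For Okbyeongpung-san, over 15762 genes, these shares were 22%, 54%, 78% and 96%, with 6 false calls. For Soshiho-tang against Yijin-tang they were 48%, 76%, 78% and 96%, with 3 false calls. Smaller fold changes were therefore missed more often, and those of 1.25 and 1.5-fold most with 2 libraries per dose. In this simulation each gene had the same spread in all groups, and vehicle had no shift of its own. The real vehicle pairs differed more than most, so the simulation does not show how many false calls arise against vehicle.

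The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, fits with only the compared groups or with all 27 libraries of replicated groups, the replicate number as a block, the estimated list correlation, and leaving out each library in turn. Using low-dose libraries in place of vehicle was added after the data were seen.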

Results

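HT29 cells were treated for 24 h with extracts of 4 traditional herbal formulas at 20, 100 and 500 µg/mL or with vehicle. The design text set each extract at 3 doses against vehicle, so the comparisons address formula and dose. Soshiho-tang and Yijin-tang had 3 libraries per dose, Okbyeongpung-san had 2, Soyo-san had 1, and vehicle had 3. Vehicle libraries held 25.4 M to 36.2 M counts.

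The vehicle libraries stood apart from all extract libraries but 1. On PC2, which held 6.2% of the variance, they lay at -19.8, -24 and -32.5, and the medium-dose Okbyeongpung-san library 2 lay at -14.1. PC1 held 11.9% of the variance and placed the Soshiho-tang libraries at 500 µg/mL farthest from the rest. Vehicle library pairs also differed more from each other than most replicate pairs, with a chi-square per degree of freedom of 11.2 to 20.6, and the medium-dose Okbyeongpung-san pair had 10.4. The names of the vehicle libraries form a set of their own, so vehicle and library set cannot be told apart. List effects of 500 µg/mL are therefore given against vehicle and against 20 µg/mL of the same formula.

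**Figure D1:**
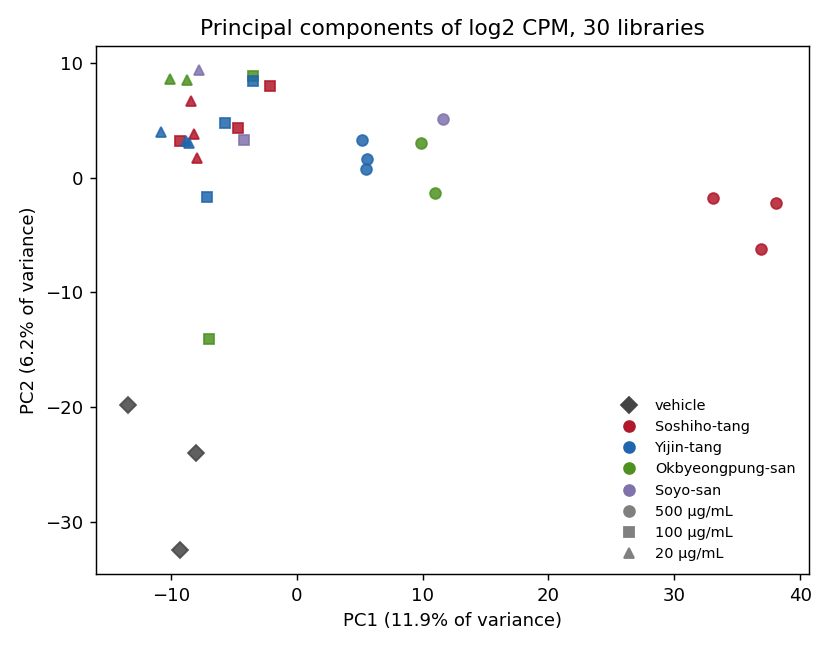
Principal components of log2 CPM, with 1 point per library, PC1 (11.9% of variance) on the horizontal and PC2 (6.2%) on the vertical axis. Colours mark vehicle or formula and shapes mark dose in µg/mL; the vehicle libraries have the lowest PC2 values, -19.8 to -32.5.

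Soshiho-tang at 500 µg/mL raised targets of the aryl hydrocarbon receptor (AHR) and of NRF2. CYP1A1, a cytochrome P450 enzyme induced through AHR, rose from 0.602 ± 0.0882 to 128 ± 4.85 CPM (SD, n = 3 each), a log2 fold change of 7.71 ± 0.29 (SE). CYP1B1, a related enzyme, rose by 3.04 ± 0.21 and the AHR target TIPARP by 1.54 ± 0.089. SLC7A11, the cystine transporter subunit, rose from 112 ± 20.5 to 414 ± 4.31 CPM. The largest falls included CD200, a membrane glycoprotein, by -2.49 ± 0.21, and ATOH1, the transcription factor of secretory cell fate in the intestine, from 4.08 ± 0.601 to 0.827 ± 0.401 CPM (log2 fold change -2.29 ± 0.21). CYP1A1 (ENSG00000140465) lies on chromosome 15 from 74719542 to 74725610, SLC7A11 (ENSG00000151012) on chromosome 4 from 138164097 to 138242349, and ATOH1 (ENSG00000172238) on chromosome 4 from 93828753 to 93830964 (GRCh38).

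Of 15882 genes tested against vehicle, 6231 changed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), 3332 higher and 2899 lower, but 2818 and 3191 with no filter on low counts. At least 2-fold changes were mostly falls, 291 against 99 rises. Against 20 µg/mL of Soshiho-tang, 4254 genes changed, 2117 higher and 2137 lower, and 361 of them by at least 2-fold (73 higher, 288 lower). Other large rises against vehicle were those of ALDH1A3, a retinaldehyde dehydrogenase (1.98 ± 0.17), the organic cation transporter SLC22A3 (1.96 ± 0.097), the adhesion receptor ADGRF1 (1.91 ± 0.074), the long noncoding RNA LUCAT1 (1.71 ± 0.2) and LRRN4 (1.54 ± 0.15). GCOM1, at 1.71 ± 0.22, overlaps neighbouring transcripts, so its reads are uncertain. Other large falls were those of NEURL1 (-2.18 ± 0.23), the urea transporter SLC14A1 (-2.05 ± 0.17), the superoxide-producing oxidase NOX1 (-1.82 ± 0.1), the Notch ligand DLL4 (-1.81 ± 0.17), the proton pump subunit ATP6V1B1 (-1.68 ± 0.095), AKAP7 (-1.65 ± 0.12) and CHST3 (-1.64 ± 0.13). The pseudogene NPY6R fell by 1.69 ± 0.18 on the log2 scale and is uncertain because other loci can share its reads. Of the changes named here, all 54 against vehicle and 29 of 30 against 20 µg/mL passed under every alternative fixed beforehand.

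Of 11 measured AHR targets, 10 rose against vehicle, none fell and 1 did not pass (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.6e-11, and adjusted p = 0.012 with an estimated correlation). With 20 µg/mL as reference, 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.5e-13, and adjusted p = 0.0034 with an estimated correlation). CYP1A1 rose by 6.94 ± 0.28, CYP1B1 by 2.56 ± 0.21, ALDH1A3 by 1.69 ± 0.17 and ALDH3A1, an aldehyde dehydrogenase, by 1.74 ± 0.11 in that comparison. UGT1A6, a glucuronosyltransferase that shares exons with its neighbours, rose by 0.73 ± 0.055 against vehicle, and the drug efflux pump ABCG2 rose by 0.57 ± 0.041. Of 8 targets of the xenobiotic receptors PXR and CAR 3 rose and 1 fell against vehicle (4 and 1 adjusted over the list alone; camera adjusted p = 0.097, and adjusted p = 0.16 with an estimated correlation). Relative to 20 µg/mL, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.086, and adjusted p = 0.12 with an estimated correlation).

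Targets of NRF2, the transcription factor of the antioxidant response, rose together. Of 24 measured, 23 rose against vehicle and 1 did not pass (23 adjusted over the list alone; camera adjusted p = 2.7e-20, and adjusted p = 0.0027 with an estimated correlation). All 24 rose against 20 µg/mL (24 adjusted over the list alone; camera adjusted p = 6.8e-32). GCLM and GCLC, the subunits of the enzyme that limits glutathione synthesis, rose by 1.47 ± 0.072 and 1.01 ± 0.047 against vehicle, and AKR1B10, an aldo-keto reductase, rose by 1.33 ± 0.048. Thioredoxin reductase TXNRD1 rose from 323 ± 14.3 to 635 ± 5.64 CPM. HMOX1, heme oxygenase, rose by 1.15 ± 0.081 against vehicle and 1.34 ± 0.085 against 20 µg/mL, and NQO1, a quinone reductase, by 0.65 ± 0.048 and 0.65 ± 0.049.

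Genes of the ATF4 and integrated stress response also rose: 14 of 23 against vehicle, with 1 lower and 8 not past the test (14 and 1 adjusted over the list alone; camera adjusted p = 4.4e-06, and adjusted p = 0.0046 with an estimated correlation). The 20 µg/mL reference gave 13 higher and 10 not past the test (15 adjusted over the list alone; camera adjusted p = 2.2e-09). ASNS, asparagine synthetase, rose by 0.76 ± 0.051 against vehicle, the serine synthesis enzyme PSAT1 by 0.53 ± 0.043 and the amino acid transporter subunit SLC3A2 by 0.64 ± 0.049. DDIT3, which encodes the stress factor CHOP, rose against 20 µg/mL (0.41 ± 0.12) and was 0.24 ± 0.12 above vehicle without passing the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.11). Without library 2 of the 20 µg/mL group, DDIT3 was at 0.36 against that dose and no longer passed. Of 20 endoplasmic reticulum chaperone genes, 12 rose against vehicle and 8 did not pass (13 adjusted over the list alone; camera adjusted p = 4.6e-05, but adjusted p = 0.12 with an estimated correlation). Relative to 20 µg/mL, 19 rose and 1 did not pass (20 adjusted over the list alone; camera adjusted p = 2.9e-13, and adjusted p = 0.013 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose by 0.36 ± 0.043 and 0.55 ± 0.043 in these comparisons, and CANX and DNAJC3 rose by 0.48 ± 0.036 and 0.5 ± 0.051 against vehicle. Of 16 amino acid and glucose transport genes, 10 rose, 2 fell and 4 did not pass against vehicle (10 and 2 adjusted over the list alone; camera adjusted p = 0.00058, but adjusted p = 0.055 with an estimated correlation). These included SLC38A2, a neutral amino acid transporter (0.72 ± 0.049), and the glucose transporter SLC2A1 (0.58 ± 0.041). From 20 to 500 µg/mL 10 of these genes rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.00047, and adjusted p = 0.041 with an estimated correlation).

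Secretory cell genes and WNT targets fell. Of 17 goblet and secretory cell genes, 11 fell against vehicle and 6 did not pass (13 lower adjusted over the list alone; camera adjusted p = 1.1e-05, but adjusted p = 0.091 with an estimated correlation). Relative to 20 µg/mL, 11 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.3e-05, but adjusted p = 0.08 with an estimated correlation). The mucin MUC2 fell from 22.2 ± 7.86 to 10.1 ± 0.362 CPM, and AGR2, which helps fold mucins, MUC13 and REG4 fell by 0.63 ± 0.076, 0.62 ± 0.062 and 0.91 ± 0.082 on the log2 scale. Of 18 WNT targets, 12 fell, 1 rose and 5 did not pass (12 and 1 adjusted over the list alone; camera adjusted p = 1e-05, and adjusted p = 0.03 with an estimated correlation), and against 20 µg/mL 11 fell (11 adjusted over the list alone; camera adjusted p = 5.2e-06, and adjusted p = 0.02 with an estimated correlation). The stem cell factor ASCL2 (-1.2 ± 0.17), the receptor EPHB3 (-1.2 ± 0.08), SP5 (-1.16 ± 0.099) and SOX4 (-0.66 ± 0.056) fell against vehicle, whereas AXIN2, a feedback gene of the pathway, was at 0.03 ± 0.052 and did not pass.

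Interferon response genes were lower: 15 of 25 fell against vehicle and 10 did not pass (15 adjusted over the list alone; camera adjusted p = 8.1e-05, but adjusted p = 0.06 with an estimated correlation). Compared with 20 µg/mL, 20 fell and 5 did not pass (22 adjusted over the list alone; camera adjusted p = 4.1e-11, and adjusted p = 0.0034 with an estimated correlation). The oligoadenylate synthetase OAS2 fell from 2.68 ± 0.312 CPM at 20 µg/mL to 0.606 ± 0.155 at 500 µg/mL, and was 1.95 ± 0.391 in vehicle. IRF9, a subunit of the interferon-activated transcription factor, fell by 0.82 ± 0.11 against vehicle on the log2 scale and by 1.01 ± 0.11 against 20 µg/mL. IFIT2 (-1 ± 0.18) and IFI6 (-0.93 ± 0.16) fell against vehicle, and IFIT1 (-1.26 ± 0.17) and IFIT3 (-0.71 ± 0.11) against 20 µg/mL.

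For other groups the 2 references differed. Of 25 cholesterol synthesis genes, 5 rose, 9 fell and 11 did not pass against vehicle (5 and 9 adjusted over the list alone; camera adjusted p = 0.21, and adjusted p = 0.71 with an estimated correlation). Compared with 20 µg/mL, 1 rose and 16 fell (2 and 16 adjusted over the list alone; camera adjusted p = 1.8e-06, but adjusted p = 0.084 with an estimated correlation). HMGCS1, the enzyme that makes hydroxymethylglutaryl-CoA, was at 161 ± 3.32 CPM, against 214 ± 4.6 at 20 µg/mL and 169 ± 11.6 in vehicle, and only the former difference passed (-0.42 ± 0.061 against -0.07 ± 0.061). INSIG1, LSS and TM7SF2 fell by 0.42 ± 0.049, 0.45 ± 0.059 and 0.64 ± 0.055 against 20 µg/mL on the log2 scale. Of 17 heat shock genes, 3 rose and 6 fell against vehicle, where the median was 0.03 and the mean -0.04 (3 and 6 adjusted over the list alone; camera adjusted p = 0.69, and adjusted p = 0.91 with an estimated correlation). Against 20 µg/mL 11 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 5.2e-06, but adjusted p = 0.12 with an estimated correlation), with FKBP4 at 0.36 ± 0.039, HSPD1 at 0.27 ± 0.045 and HSPH1 at 0.35 ± 0.059. Immediate early genes rose against 20 µg/mL, 12 of 21 with 1 lower and 8 not past the test (13 and 1 adjusted over the list alone; camera adjusted p = 4.9e-07, but adjusted p = 0.052 with an estimated correlation). With vehicle as reference 11 rose and 6 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.061, and adjusted p = 0.49 with an estimated correlation). The phosphatase DUSP5 rose by 1.21 ± 0.11 and the transcription factor FOSL1 by 0.78 ± 0.063 against 20 µg/mL.

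Genes of DNA replication rose against vehicle, 21 of 30 with 1 lower and 8 not past the test (21 and 1 adjusted over the list alone; camera adjusted p = 3.6e-06, but adjusted p = 0.067 with an estimated correlation). From 20 to 500 µg/mL 16 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.4e-06, but adjusted p = 0.058 with an estimated correlation). CDC6, which loads replication helicases, rose by 0.47 ± 0.041 and the clamp loader subunit RFC3 by 0.56 ± 0.053 against vehicle. The proliferation marker MKI67 was 1110 ± 52.1 CPM against 1040 ± 101 in vehicle and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.15). The cell cycle inhibitor CDKN1A rose by 0.35 ± 0.081 and the chemokine CXCL8 by 0.41 ± 0.093. Of 13 mitochondrially encoded genes, 8 fell against vehicle and 5 did not pass (10 lower adjusted over the list alone; camera adjusted p = 8.6e-05, but adjusted p = 0.37 with an estimated correlation), among them MT-ND6 (-0.69 ± 0.13) and MT-CO1 (-0.4 ± 0.087). Only 1 fell from 20 to 500 µg/mL (none adjusted over the list alone; camera adjusted p = 0.019, but adjusted p = 0.53 with an estimated correlation). Mitochondrial genes held 11.5% to 13.9% of counts in the vehicle libraries and 9.06% to 10.8% at 500 µg/mL of Soshiho-tang. In all, 16 of 30 lists passed against vehicle, and 4 of them with an estimated correlation. With only the 6 libraries compared and the preset correlation, 15 lists passed, and 16 did in another split of these libraries.

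**Figure D2:**
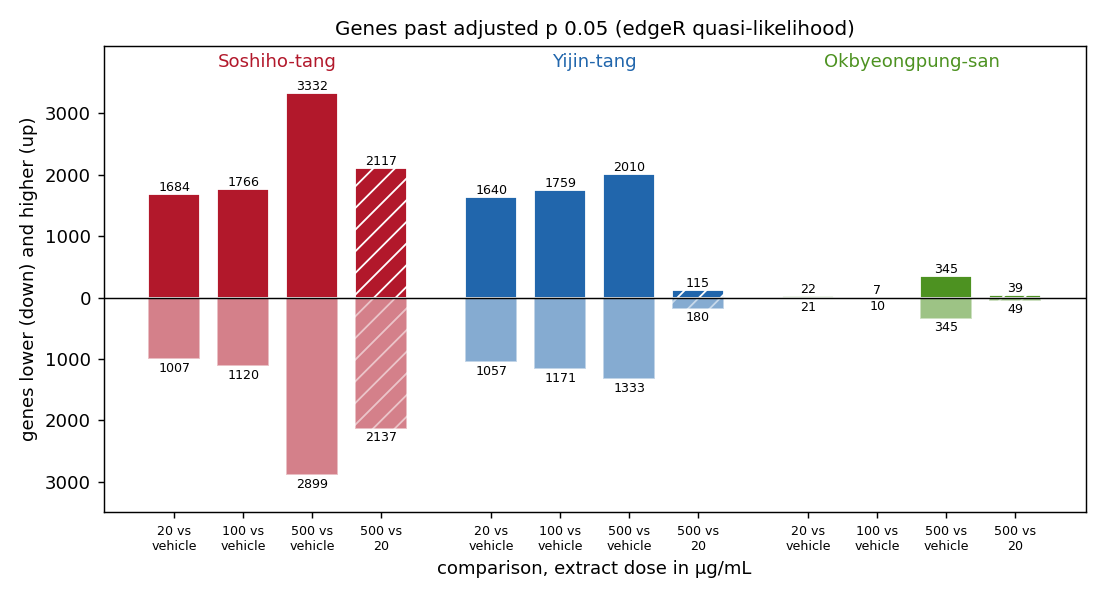
Numbers of genes past an adjusted p of 0.05 (edgeR quasi-likelihood), higher above and lower below the zero line, for each dose in µg/mL against vehicle (plain bars) and for 500 against 20 µg/mL (hatched). Soshiho-tang at 500 µg/mL (n = 3) has 3332 higher and 2899 lower genes against vehicle. Okbyeongpung-san (n = 2, separate fit) has 345 and 345. With all 27 libraries these are 3128 and 3077, and 1616 and 1375.

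Yijin-tang at 500 µg/mL raised AHR targets and the cholesterol efflux transporters. CYP1A1 rose from 0.602 ± 0.0882 to 7.72 ± 1.53 CPM (SD, n = 3 each), a log2 fold change of 3.69 ± 0.42 (SE), and CYP1B1 by 1.22 ± 0.21. ABCG1, a sterol transporter induced by the liver X receptor (LXR), rose from 1.85 ± 0.349 to 7.57 ± 0.68 CPM (2.03 ± 0.13), and its relative ABCA1 by 0.9 ± 0.14. ABCG1 (ENSG00000160179) lies on chromosome 21 from 42199689 to 42297244. SLC7A11 rose by 0.91 ± 0.094. The falls were smaller: DEPP1, a FOXO target, fell by 0.91 ± 0.16 on the log2 scale and the matricellular protein gene CCN2 by 0.84 ± 0.14.

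Against vehicle 3343 of 15882 genes changed, 2010 higher and 1333 lower, but 1593 and 1663 with no filter on low counts. Of the 3343, 66 changed by at least 2-fold. Between 500 and 20 µg/mL of Yijin-tang 295 changed, 115 higher and 180 lower, and 4 by at least 2-fold. That count fell to 147 without library 1 and 173 without library 3 of the 500 µg/mL group, and to 156 and 175 without libraries 2 and 3 of the 20 µg/mL group. TMCC3 (0.87 ± 0.075), ADGRF1 (0.86 ± 0.075), the splicing kinase CLK1 (0.85 ± 0.069) and KBTBD8 (0.82 ± 0.16) were among the largest rises against vehicle, with GCOM1, an uncertain overlapping locus, at 1 ± 0.23. RASSF10 (-0.85 ± 0.12), LDLRAD2 (-0.84 ± 0.19), ANXA13 (-0.8 ± 0.15), FAM131B (-0.75 ± 0.12) and C2orf72 (-0.75 ± 0.19) were among the largest falls. FAM156B (-1.13 ± 0.37), which has a near copy, and the ribosomal protein pseudogenes RPL23AP42 (-1.09 ± 0.26) and RPL24P4 (-0.83 ± 0.21) are uncertain because their reads can be shared. Calls were lost in 6 settings for FAM156B (-1.3 to -0.97), in 1 for RPL23AP42 (-1.1) and in 1 for RPL24P4 (-0.61). MUC2 was 14.5 ± 1.53 against 22.2 ± 7.86 CPM and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.051). Of the changes named here, 26 of 30 against vehicle and 14 of 21 against 20 µg/mL passed under every alternative fixed beforehand, and 1 more against vehicle, C2orf72, passed in all but DESeq2, where it had no adjusted p. Those alternatives keep vehicle as the reference for changes against vehicle. With 20 µg/mL of Soshiho-tang in its place 280 genes changed, and CLK1 and FAM156B turned in sign.

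Of 11 AHR targets 9 rose against vehicle and 2 did not pass (9 adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.049 with an estimated correlation). From 20 to 500 µg/mL 7 rose and 4 did not pass (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.3e-16, and adjusted p = 0.002 with an estimated correlation). CYP1A1 rose by 3.21 ± 0.41 and ALDH3A1 by 0.88 ± 0.11 in that comparison, and CYP1B1 by 0.93 ± 0.21. The CYP1B1 call was lost without any 1 of the 6 libraries compared (0.87 to 0.98) and in 8 settings in all. Of 24 NRF2 targets 12 rose and 12 did not pass against vehicle (12 adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.049 with an estimated correlation), and likewise against 20 µg/mL (20 adjusted over the list alone; camera adjusted p = 4.1e-30). GCLM rose by 0.72 ± 0.073, GCLC by 0.47 ± 0.048 and NQO1 by 0.31 ± 0.048 against vehicle. Against 20 µg/mL AKR1B10 rose by 0.64 ± 0.049, TXNRD1 by 0.36 ± 0.055, NQO1 by 0.29 ± 0.048 and AKR1C2, whose close paralogs share reads, by 0.78 ± 0.09. HMOX1 was 0.12 ± 0.087 above vehicle and 0.32 ± 0.091 above 20 µg/mL, and neither passed. Of 8 LXR targets 7 rose against vehicle and 1 did not pass (7 adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.0051 with an estimated correlation), and 4 rose against 20 µg/mL (6 adjusted over the list alone; camera adjusted p = 2.9e-09). ABCG1 rose by 1.59 ± 0.13 and MYLIP, which triggers degradation of the LDL receptor, by 0.45 ± 0.069 against 20 µg/mL, and SCD and LPCAT3, enzymes of fatty acid desaturation and phospholipid remodelling, by 0.29 ± 0.039 and 0.3 ± 0.044 against vehicle.

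Cholesterol synthesis genes fell with dose in Yijin-tang. Against 20 µg/mL 16 of 25 fell and 9 did not pass (24 adjusted over the list alone; camera adjusted p = 1.1e-34, and adjusted p = 0.00068 with an estimated correlation). Against vehicle 6 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00014, but adjusted p = 0.29 with an estimated correlation). HMGCS1 was 152 ± 6.57 CPM against 214 ± 3.95 at 20 µg/mL (-0.49 ± 0.061), and INSIG1 (-0.49 ± 0.049), SQLE (-0.28 ± 0.039) and acetyl-CoA synthetase ACSS2 (-0.72 ± 0.11) also fell. Of 25 interferon response genes 4 fell against 20 µg/mL (9 adjusted over the list alone; camera adjusted p = 2.2e-09, and adjusted p = 0.0053 with an estimated correlation), with IFIT1 at -0.99 ± 0.16, DDX60 at -0.81 ± 0.19 and IRF9 at -0.46 ± 0.099. Against vehicle 3 fell and 1 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.087, and adjusted p = 0.42 with an estimated correlation). Of 30 DNA replication genes 20 rose against vehicle (22 adjusted over the list alone; camera adjusted p = 1.6e-10, and adjusted p = 0.041 with an estimated correlation) and 3 against 20 µg/mL (14 adjusted over the list alone; camera adjusted p = 2.9e-16, and adjusted p = 0.0033 with an estimated correlation). RFC3 rose by 0.49 ± 0.053 and MCM6 by 0.25 ± 0.04 against vehicle. MCM2 (0.16 ± 0.039) and RRM2 (0.14 ± 0.034) rose, and IFI44 (-0.57 ± 0.15) fell, against 20 µg/mL in calls lost in 6, 6 and 7 of the alternative settings. The largest other changes against 20 µg/mL were those of PHLDB2 (0.89 ± 0.21) and the deiodinase IYD (-0.82 ± 0.16). The DDX60, IRF9 and PHLDB2 calls were lost in 3, 1 and 4 of the leave-one-out settings, where DDX60 was -0.79 to -0.69, IRF9 -0.45 and PHLDB2 0.69 to 0.86.

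Heat shock genes fell against vehicle, 10 of 17 with 1 higher (10 and 2 adjusted over the list alone; camera adjusted p = 7.7e-05, but adjusted p = 0.29 with an estimated correlation), whereas none of 17 passed against 20 µg/mL (none adjusted over the list alone; camera adjusted p = 0.02, but adjusted p = 0.55 with an estimated correlation). HSPA1A, which has a near-identical paralog, fell from 301 ± 16.9 to 218 ± 0.72 CPM and HSPA8 from 3030 ± 220 to 2370 ± 74.9 CPM. Of 18 WNT targets 7 fell and 1 rose against vehicle (7 and 1 adjusted over the list alone; camera adjusted p = 0.00046, but adjusted p = 0.08 with an estimated correlation). With 20 µg/mL as reference none of them fell and 1 rose (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00098, but adjusted p = 0.08 with an estimated correlation). Of 17 goblet and secretory cell genes 5 fell against vehicle (6 adjusted over the list alone; camera adjusted p = 0.00025, but adjusted p = 0.24 with an estimated correlation) and 1 against 20 µg/mL (2 adjusted over the list alone; camera adjusted p = 0.011, but adjusted p = 0.33 with an estimated correlation). In all, 13 lists passed against vehicle and 4 of them with an estimated correlation. With only the 6 libraries compared and the preset correlation, 13 lists passed, and 15 did in another split of these libraries. Mitochondrial genes held 10.1% to 12.4% of counts at 500 µg/mL of Yijin-tang.

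Okbyeongpung-san at 500 µg/mL raised AHR and NRF2 targets and lowered cholesterol synthesis genes. CYP1A1 rose from 0.602 ± 0.0882 (SD, n = 3) to 3.46 ± 0.919 CPM (n = 2), a log2 fold change of 2.52 ± 0.25 (SE), and CYP1B1 by 0.95 ± 0.071. AKR1B10 rose from 105 ± 3.6 to 211 ± 0.289 CPM (1.01 ± 0.061), GCLM by 1 ± 0.097 and SLC7A11 by 1.29 ± 0.13. ABCG1 rose by 1.32 ± 0.18. INSIG1, which restrains sterol synthesis and is itself sterol-responsive, fell from 125 ± 4.43 to 85.4 ± 3.07 CPM (-0.55 ± 0.063). AKR1B10 (ENSG00000198074) lies on chromosome 7 from 134527592 to 134541408, and INSIG1 (ENSG00000186480) on chromosome 7 from 155297776 to 155310235.

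Of 15762 genes 690 changed against vehicle, 345 higher and 345 lower, 41 by at least 2-fold. The count was 55 and 58 without Okbyeongpung-san library 2 or 3, 171 without vehicle library 3, and 1279 and 1358 without vehicle library 1 or 2. Between 500 and 20 µg/mL 88 changed, 39 higher and 49 lower, and this became 18, 15, 21 and 12 without library 2 or 3 at 500 µg/mL and library 2 or 3 at 20 µg/mL. Other large rises against vehicle were those of the amino acid transporter SLC38A4 (1.24 ± 0.13), AADAC (0.97 ± 0.16) and, with close paralogs that can share reads, AKR1C2 (1.04 ± 0.099) and AKR1C3 (1.02 ± 0.076). Large falls were those of VGLL1 (-1.14 ± 0.16), ATP6V1B1 (-1.06 ± 0.096), SLC14A1 (-1.02 ± 0.16), SLC6A20 (-0.99 ± 0.15), CD200 (-0.95 ± 0.14), RASSF10 (-0.94 ± 0.12), CLIC3 (-0.9 ± 0.14) and CLIC5 (-0.87 ± 0.12). PKD1P6-NPIPP1 (-1.13 ± 0.25) is a readthrough of repeated loci and uncertain. Without library 2 or 3 at 500 µg/mL the calls of VGLL1 (-1.22 and -1.08), SLC14A1 (-1.1 and -0.96), CD200 (-0.94 and -0.95), CLIC3 (-0.9 and -0.89) and PKD1P6-NPIPP1 (-0.97 and -1.27) were lost, as were those of AADAC without library 2 (0.87) and of SLC6A20 (-0.85) and CLIC5 (-0.71) without library 3. Without vehicle library 3 the call of PKD1P6-NPIPP1 (-0.97) was lost too. Of the changes named here, 15 of 32 against vehicle and 6 of 17 against 20 µg/mL passed under every alternative fixed beforehand. A further 3 against vehicle, CYP1A1, ABCG1 and SLC38A4, passed in all but DESeq2, where they had no adjusted p. Here too the alternatives keep vehicle as the reference for changes against vehicle.

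Of 11 AHR targets 8 rose against vehicle and 3 did not pass (8 adjusted over the list alone; camera adjusted p = 6.4e-13, and adjusted p = 0.014 with an estimated correlation), and 6 rose against 20 µg/mL (9 adjusted over the list alone; camera adjusted p = 4.3e-19, and adjusted p = 0.002 with an estimated correlation). ABCG2 rose by 0.78 ± 0.061 and ALDH3A1 by 0.84 ± 0.084 against vehicle, and CYP1A1 by 2.76 ± 0.31 and ALDH3A1 by 1.11 ± 0.096 against 20 µg/mL. Of 24 NRF2 targets 16 rose against vehicle and 8 did not pass (18 adjusted over the list alone; camera adjusted p = 1.6e-22, and adjusted p = 0.014 with an estimated correlation), and 12 rose against 20 µg/mL (21 adjusted over the list alone; camera adjusted p = 6.1e-45, and adjusted p = 0.002 with an estimated correlation). HMOX1 rose by 0.79 ± 0.14, NQO1 by 0.51 ± 0.06 and GCLC by 0.69 ± 0.069 against vehicle. HMOX1 did not pass against vehicle without library 2 or 3 at 500 µg/mL (0.69 and 0.88), nor against 20 µg/mL without any 1 of the 4 libraries (0.87 to 1.15). The NQO1 call against 20 µg/mL was likewise lost without any 1 of these (0.42 to 0.48). Against 20 µg/mL AKR1B10 rose by 1.14 ± 0.068, HMOX1 by 1 ± 0.16 and NQO1 by 0.45 ± 0.067, and AKR1C2 and AKR1C3 by 1.12 ± 0.11 and 1.01 ± 0.085.

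Of 25 cholesterol synthesis genes 12 fell against vehicle and 13 did not pass (18 adjusted over the list alone; camera adjusted p = 6.4e-13, and adjusted p = 0.018 with an estimated correlation), and 7 fell against 20 µg/mL (20 adjusted over the list alone; camera adjusted p = 1e-31, and adjusted p = 0.002 with an estimated correlation). TM7SF2 (-0.64 ± 0.075), LSS (-0.47 ± 0.076) and MVD (-0.4 ± 0.071) fell against vehicle. HMGCS1 was 139 ± 5.76 CPM, against 202 ± 5.57 at 20 µg/mL (-0.54 ± 0.082, past the test) and 169 ± 11.6 in vehicle (-0.28 ± 0.075, not past it). INSIG1, LSS and TM7SF2 fell by 0.7 ± 0.069, 0.55 ± 0.083 and 0.52 ± 0.082 against 20 µg/mL on the log2 scale. Without any 1 of the 4 libraries the calls against 20 µg/mL of HMGCS1 (-0.58 to -0.49), LSS (-0.57 to -0.54) and TM7SF2 (-0.53 to -0.51) were lost. Without library 2 or 3 at 500 µg/mL those of LSS (-0.48 and -0.45) and MVD (-0.43 and -0.36) against vehicle were lost. Of 8 LXR targets 3 rose against vehicle (4 adjusted over the list alone; camera adjusted p = 0.0094, but adjusted p = 0.2 with an estimated correlation) and none passed against 20 µg/mL (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.15, and adjusted p = 0.45 with an estimated correlation). Of 17 goblet and secretory cell genes 5 fell against vehicle (7 adjusted over the list alone; camera adjusted p = 7.2e-06, but adjusted p = 0.061 with an estimated correlation) and 2 against 20 µg/mL (4 adjusted over the list alone; camera adjusted p = 1.2e-06, and adjusted p = 0.037 with an estimated correlation). REG4 (-0.87 ± 0.11), MUC13 (-0.47 ± 0.069) and the secretory transcription factors SPDEF (-0.42 ± 0.087) and FOXA3 (-0.55 ± 0.12) fell against vehicle, and REG4 and MUC13 also against 20 µg/mL (-0.61 ± 0.12 and -0.49 ± 0.075). These calls of REG4 (-0.68 to -0.53) and MUC13 (-0.56 to -0.43) against 20 µg/mL were lost without any 1 of the 4 libraries. Those of MUC13 (-0.49 and -0.46), SPDEF (-0.49 and -0.36) and FOXA3 (-0.61 and -0.5) against vehicle were lost without library 2 or 3 at 500 µg/mL, and those of SPDEF (-0.39) and FOXA3 (-0.53) also without vehicle library 3. MUC2 was 10.7 ± 1.84 CPM and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.12).

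Of 25 interferon response genes, only IFIT1 (-1.17 ± 0.16) fell against 20 µg/mL of Okbyeongpung-san (6 lower adjusted over the list alone; camera adjusted p = 4.8e-14, and adjusted p = 0.032 with an estimated correlation). None passed against vehicle (none adjusted over the list alone; camera adjusted p = 0.034, but adjusted p = 0.39 with an estimated correlation). Of 13 mitochondrially encoded genes 1 fell against vehicle (10 adjusted over the list alone; camera adjusted p = 4.5e-07, but adjusted p = 0.32 with an estimated correlation). None fell against 20 µg/mL (none adjusted over the list alone; camera adjusted p = 0.84, and adjusted p = 0.94 with an estimated correlation), and these genes held 10.3% to 10.4% of counts at 500 µg/mL. SLC6A20, a proline transporter, and VGLL1 fell by 1.16 ± 0.17 and 1.04 ± 0.18, and CTTNBP2 by 1.04 ± 0.21, against 20 µg/mL on the log2 scale. The calls of VGLL1 (-1.12 to -0.96) and CTTNBP2 (-1.47 to -0.78) were lost without any 1 of the 4 libraries, and that of SLC6A20 without library 3 at 500 or 20 µg/mL (-1.03 and -1.06). The IFIT1 call was lost without library 2 or 3 at 500 µg/mL (-1.15 and -1.19) and without library 3 at 20 µg/mL (-1.1). Of 17 heat shock genes 6 fell against vehicle (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00084, but adjusted p = 0.39 with an estimated correlation), and of 18 WNT targets 4 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00074, but adjusted p = 0.096 with an estimated correlation). With 20 µg/mL as reference none of the heat shock genes passed (none adjusted over the list alone; camera adjusted p = 0.006 for a rise, but adjusted p = 0.48 with an estimated correlation). None of the WNT targets passed (3 lower adjusted over the list alone; camera adjusted p = 0.22, and adjusted p = 0.46 with an estimated correlation). In all, 16 lists passed against vehicle and 3 of them with an estimated correlation.

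**Figure D3:**
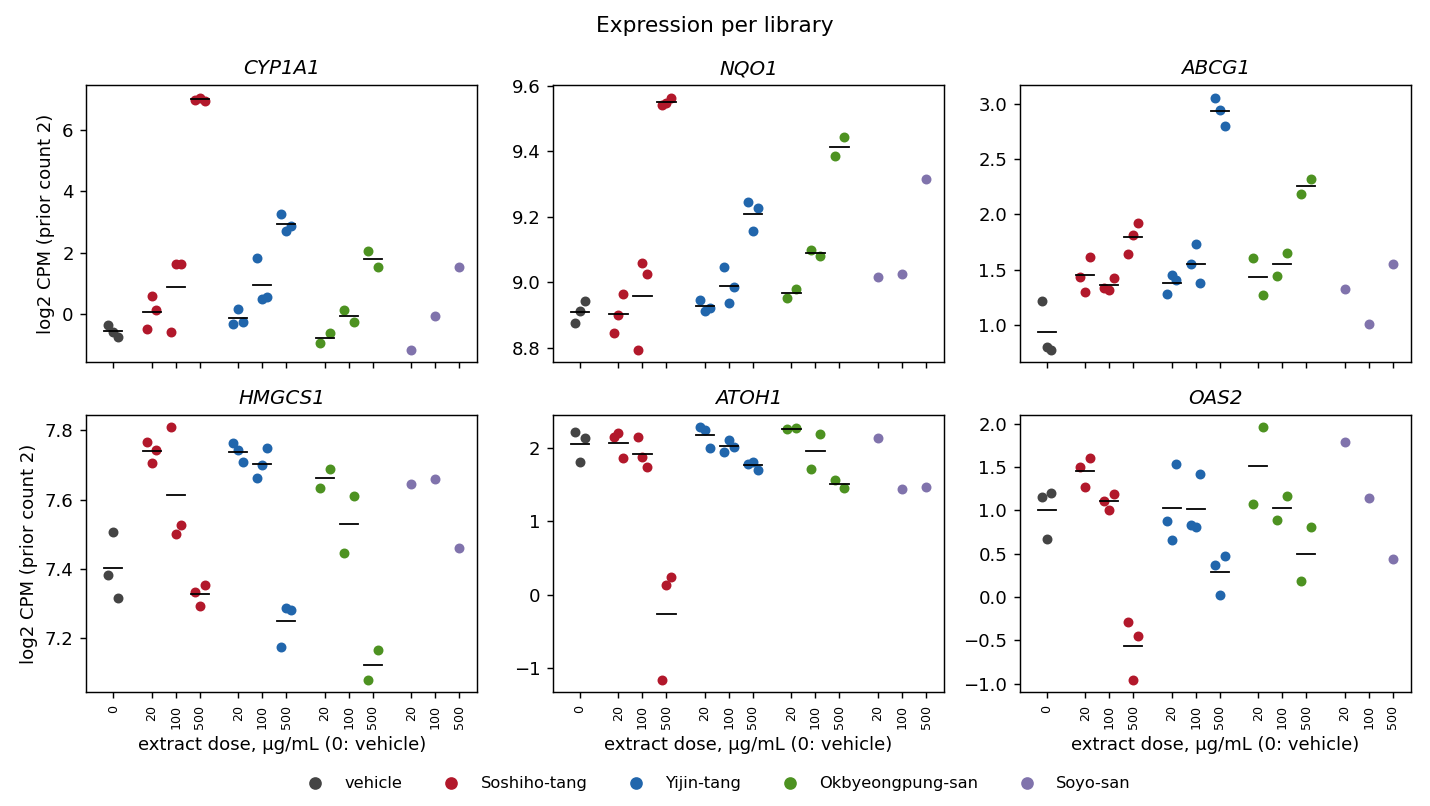
Log2 CPM (prior count 2) of 6 genes in each library, by dose in µg/mL with vehicle at 0; points are libraries and bars are group means where a group has at least 2 libraries. Mean CYP1A1 at 500 µg/mL of Soshiho-tang was 128 CPM, against 7.72 for Yijin-tang, 3.46 for Okbyeongpung-san and 0.602 for vehicle.

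At 100 and 20 µg/mL all groups were set against the same 3 vehicle libraries, so changes they share need not come from the extracts. The splicing kinase CLK1 was higher than vehicle, at 32.4 ± 2.33 CPM, in every one of these groups, with log2 fold changes of 0.83 ± 0.07 and 0.9 ± 0.069 for Soshiho-tang at 100 and 20 µg/mL, 0.89 ± 0.069 and 0.86 ± 0.069 for Yijin-tang, and 0.78 ± 0.077 and 0.81 ± 0.077 for Okbyeongpung-san. CYP1A1 rose at 100 µg/mL of Soshiho-tang (2.2 ± 1.4 CPM, 1.89 ± 0.56) and of Yijin-tang (2.06 ± 1.21 CPM, 1.76 ± 0.57). These calls were lost in 7 and 6 of the alternative settings. They were lost without any 1 of vehicle libraries 1, 2 and 3 (2.02, 1.86 and 1.78 for Soshiho-tang, 1.89, 1.73 and 1.65 for Yijin-tang), without Soshiho-tang library 2 or 3 (1.63 and 1.56) and without Yijin-tang library 1 (1.15). It did not pass at 20 µg/mL (0.78 ± 0.67 and 0.48 ± 0.7) or for Okbyeongpung-san (0.55 ± 0.31 and -0.25 ± 0.35).

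Against vehicle 2886 genes changed at 100 µg/mL of Soshiho-tang (1766 higher, 1120 lower) and 2691 at 20 µg/mL (1684 and 1007). For Yijin-tang these were 2930 (1759 and 1171) and 2697 (1640 and 1057). With no filter on low counts the balance turned in all 4, to 1373 and 1554, 1271 and 1434, 1359 and 1567, and 1311 and 1453. With only the compared groups in the fit, far fewer genes were called at 100 and 20 µg/mL. These were 559 and 362 for Soshiho-tang, and 574 and 498 for Yijin-tang. Without vehicle library 3, 1733 genes were called at 20 µg/mL of Soshiho-tang and 1788 at 20 µg/mL of Yijin-tang. The counts were 1533 without Soshiho-tang library 3, and 1717 and 1707 without Yijin-tang library 2 or 3. Medium and low doses of the same formula did not differ past the test in edgeR: 0 genes for Soshiho-tang (474 at unadjusted p below 0.05, 0 with DESeq2), 0 for Yijin-tang (509, and 0 with DESeq2) and 0 for Okbyeongpung-san (369, and 2 with DESeq2). The counts at unadjusted p are under a share of 0.05 of the genes, so the test may be too strict for these pairs. For Okbyeongpung-san the counts against vehicle at 100 and 20 µg/mL depended strongly on the fit. They were 90 and 468 with the replicate block, 157 and 545 with DESeq2, and 1489 and 2457 with all 27 libraries. In the main fit 17 genes changed against vehicle at 100 µg/mL of Okbyeongpung-san and 43 at 20 µg/mL. The former count was 199, 318 and 3 without vehicle library 1, 2 or 3, and 3 and 5 without Okbyeongpung-san library 2 or 3. The latter count was 776, 913 and 5 without these vehicle libraries, and 2 without Okbyeongpung-san library 2. Without library 3 it was 0 in edgeR, with 1659 genes at unadjusted p below 0.05 and 25 in DESeq2.

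The largest changes against vehicle at 100 µg/mL of Soshiho-tang included the double-stranded RNA sensor TLR3 (0.88 ± 0.17) and KLHL28 (0.75 ± 0.091), with falls in the ribosomal protein pseudogenes RPL24P4 (-0.85 ± 0.21), RPL12P16 (-0.84 ± 0.17) and RPL23AP42 (-0.83 ± 0.25). At 20 µg/mL they were PEDS1-UBE2V1 (0.97 ± 0.23), GCOM1 (0.96 ± 0.23), FAM156B (-1.22 ± 0.38), RPL23AP42 (-1.02 ± 0.26) and NPIPB13 (-0.98 ± 0.25). For Yijin-tang LY75-CD302 (0.9 ± 0.22), CYP1B1 (0.78 ± 0.21), NPIPB13 (-1.04 ± 0.25), the keratin KRT17 (-0.82 ± 0.13) and CCN2 (-0.77 ± 0.14) led at 100 µg/mL. GCOM1 (1.03 ± 0.23), CTAGE8 (0.95 ± 0.23), RPL23AP42 (-0.97 ± 0.25), RPL32P18 (-0.88 ± 0.21) and KRT17 (-0.81 ± 0.13) led at 20 µg/mL. Pseudogenes, readthrough loci, GCOM1 and the FAM156B, NPIPB13 and CTAGE8 families share reads with other loci and are uncertain. For Okbyeongpung-san the kinase FRK rose by 0.61 ± 0.1 and 0.67 ± 0.1 at 100 and 20 µg/mL, TMCC3 by 0.56 ± 0.095 at 100 µg/mL and ABCA1 by 0.78 ± 0.11 at 20 µg/mL. HSPA1A (-0.61 ± 0.07), TNS4 (-0.52 ± 0.076) and KLF6 (-0.51 ± 0.073) fell at 100 µg/mL, and the phosphatase DUSP1 (-0.68 ± 0.13), MT-ND6 (-0.68 ± 0.12) and SAMD1 (-0.53 ± 0.089) at 20 µg/mL. Not all of these changes held: of those named, 4 of 7 at 100 and 3 of 7 at 20 µg/mL of Soshiho-tang, 4 of 7 at each dose of Yijin-tang, and 1 of 6 at 100 and 0 of 6 at 20 µg/mL of Okbyeongpung-san passed under every alternative fixed beforehand.

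Of 17 heat shock genes 9 fell at 20 µg/mL of Soshiho-tang (11 adjusted over the list alone; camera adjusted p = 5.5e-08, but adjusted p = 0.34 with an estimated correlation). For Yijin-tang 10 fell (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.8e-08, but adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes were higher than vehicle at 20 µg/mL, 9 of 25 for Soshiho-tang (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00019, but adjusted p = 0.39 with an estimated correlation). For Yijin-tang 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2.1e-05, but adjusted p = 0.29 with an estimated correlation). HMGCS1 rose by 0.35 ± 0.06 and 0.34 ± 0.06 at these doses. Of 21 immediate early genes 7 fell and 1 rose at 20 µg/mL of each formula (8 and 1 adjusted over the list alone for Soshiho-tang, camera adjusted p = 0.00019, but adjusted p = 0.34 with an estimated correlation; 9 and 1 for Yijin-tang, camera adjusted p = 0.0022, but adjusted p = 0.35 with an estimated correlation). Of 25 interferon response genes 8 rose at 20 µg/mL of Soshiho-tang (8 adjusted over the list alone; camera adjusted p = 0.004, but adjusted p = 0.34 with an estimated correlation).

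Soshiho-tang and Yijin-tang were compared directly at each dose, with vehicle in the shared fit but not in the contrast. At 500 µg/mL CYP1A1 was 128 ± 4.85 CPM with Soshiho-tang and 7.72 ± 1.53 with Yijin-tang (SD, n = 3 each), a log2 difference of 4.03 ± 0.2 (SE). CYP1B1 (1.82 ± 0.2), SLC22A3 (1.25 ± 0.093), ALDH1A3 (1.23 ± 0.16), the membrane protein gene EMP1 (1.09 ± 0.053) and HMOX1 (1.03 ± 0.082) were also higher with Soshiho-tang. CD200 (-2.13 ± 0.22), ATOH1 (-1.98 ± 0.22), NOX1 (-1.67 ± 0.11), DLL4 (-1.4 ± 0.18) and GABRP, a GABA receptor subunit (-1.39 ± 0.11), were lower. The sterol transporters ABCG1 (-1.16 ± 0.13) and ABCA1 (-1.01 ± 0.14) were lower with Soshiho-tang than with Yijin-tang.

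In that comparison 2052 of 15882 genes differed, 1039 higher and 1013 lower with Soshiho-tang, 134 of them by at least 2-fold. Of the 27 named here, 25 passed under every alternative fixed beforehand. Of 24 NRF2 targets 22 were higher and 2 did not pass (22 adjusted over the list alone; camera adjusted p = 2e-31, and adjusted p = 0.00014 with an estimated correlation), with NQO1 at 0.34 ± 0.048. Of 11 AHR targets 9 were higher and 2 did not pass (9 adjusted over the list alone; camera adjusted p = 6e-15, and adjusted p = 0.0031 with an estimated correlation). Of 23 ATF4 and stress response genes 14 were higher and 9 did not pass (18 adjusted over the list alone; camera adjusted p = 2.9e-15, and adjusted p = 5.4e-05 with an estimated correlation), among them ASNS (0.77 ± 0.051), TRIB3 (0.58 ± 0.063), SLC3A2 (0.46 ± 0.049) and DDIT3 (0.47 ± 0.12, but 0.42 and not past the test without Yijin-tang library 1). Of 20 endoplasmic reticulum chaperone genes 12 were higher (16 adjusted over the list alone; camera adjusted p = 3e-11, and adjusted p = 0.017 with an estimated correlation). Of 21 immediate early genes 12 were higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 1.4e-09, and adjusted p = 0.018 with an estimated correlation), with DUSP5 at 0.95 ± 0.11 and FOSL1 at 0.6 ± 0.062. CXCL8 (0.51 ± 0.096), CDKN1A (0.46 ± 0.084) and the laminin gene LAMA3 (0.9 ± 0.057) were higher too.

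Of 8 LXR targets 5 were lower with Soshiho-tang and 3 did not pass (5 adjusted over the list alone; camera adjusted p = 8e-05, and adjusted p = 0.012 with an estimated correlation). Of 18 WNT targets 8 were lower (9 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.022 with an estimated correlation), with ASCL2 at -0.88 ± 0.18 and EPHB3 at -0.88 ± 0.083. Of 25 interferon response genes 5 were lower (8 adjusted over the list alone; camera adjusted p = 1.8e-05, and adjusted p = 0.023 with an estimated correlation), with IRF9 at -0.68 ± 0.11 and OAS2 at -0.97 ± 0.3. The OAS2 call was lost without Soshiho-tang library 2 or 3 (-0.74 and -1.03) and without Yijin-tang library 1 or 3 (-0.94 and -0.87). Of 17 goblet and secretory cell genes 8 were lower (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00019, but adjusted p = 0.12 with an estimated correlation). In all, 18 lists passed and 14 with an estimated correlation.

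At 100 µg/mL no gene differed between Soshiho-tang and Yijin-tang in edgeR (0 of 15882, 342 at unadjusted p below 0.05, 1 gene with DESeq2), and at 20 µg/mL likewise (0, 339 and 1). Both 342 and 339 are under the share of 0.05 that would pass if no gene differed. The test may thus be too strict here, and the zeros alone do not show equality. With only the compared groups in the fit, 2 and 5 genes differed. Of 9271 genes with a mean of at least 10 CPM, 9249 (99.8%) had a 95% interval of the difference within 1.5-fold either way at 100 µg/mL and 9246 (99.7%) at 20 µg/mL. For NQO1 the intervals ran from -0.13 to 0.08 and from -0.12 to 0.08 on the log2 scale, and for HMGCS1 from -0.21 to 0.04 and from -0.13 to 0.13. For CYP1A1 they were wide, from -0.82 to 1.08 and from -1.09 to 1.69, so a difference of 1.5-fold was not excluded.

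The changes from 20 to 500 µg/mL were compared between formulas, which share no libraries in that contrast. Of the 295 genes changed in Yijin-tang 288 (97.6%) had the same sign in Soshiho-tang. In both, 103 genes were higher (15.3 for independent lists) and 160 lower (24.2), and 1 went opposite ways. Across 15882 genes, which are not independent replicates, Pearson's r was 0.243 and Spearman's rho 0.444. Pearson's r was 0.764 for genes with a mean of at least 10 CPM. Over all genes it was 0.154, 0.21 and 0.167 without replicate 1, 2 or 3. Of the 88 genes changed in Okbyeongpung-san, 87 had the same sign in Soshiho-tang and 82 in Yijin-tang, over 15611 genes tested in both. With Soshiho-tang 38 were higher in both (5.28 for independent lists) and 47 lower in both (6.66). With Yijin-tang these were 25 (0.29) and 34 (0.56).

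**Figure D4:**
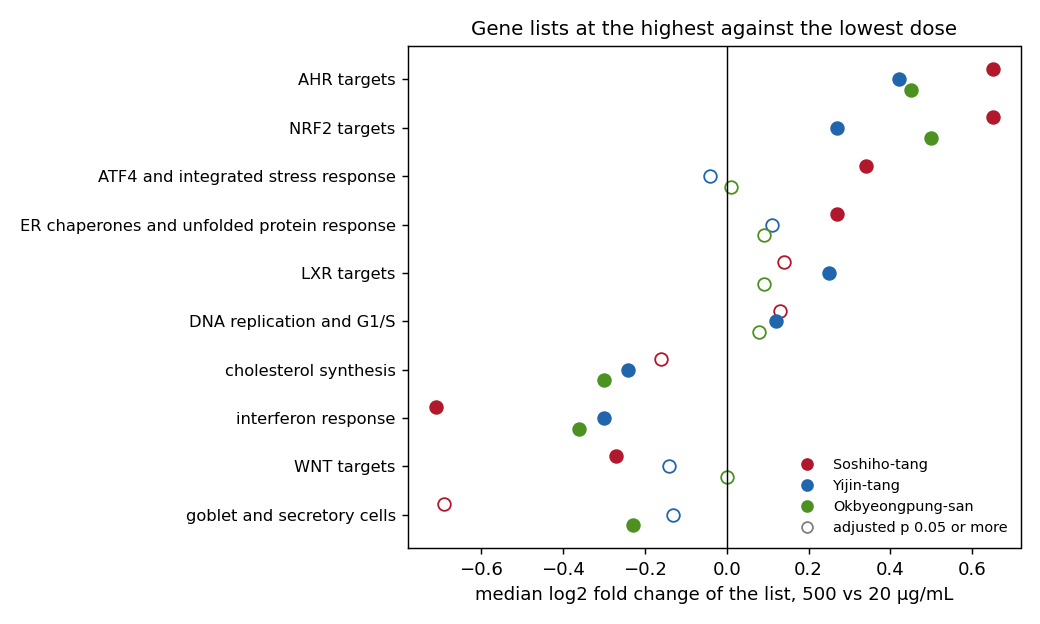
Median log2 fold change from 20 to 500 µg/mL of 10 gene lists, with 1 point per formula; open points have an adjusted p of 0.05 or more with an estimated correlation. AHR and NRF2 targets have medians above 0 in Soshiho-tang (0.65 and 0.65), Yijin-tang (0.42 and 0.27) and Okbyeongpung-san (0.45 and 0.5).

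Soyo-san had 1 library per dose, so its values have no replicate check and no test. Titles place these libraries in batch D and vehicle in batch E, so a difference from vehicle is also a difference between these batches. At 500 µg/mL CYP1A1 was 2.78 CPM, against 0.597 ± 0.0906 in vehicle (SD, n = 3), a log2 difference of 2.1, and 0.361 CPM at 20 µg/mL. SLC7A11 (1.23), GCLM (0.96), AKR1C3 (0.89) and AKR1B10 (0.87) were above the vehicle mean, and the readthrough loci POC1B-GALNT4 (1.15) and BCL2L2-PABPN1 (0.9) are uncertain. IFITM3 (-0.87), PRR36 (-0.86), IRF9 (-0.86), MUC2 (-0.85) and CLIC3 (-0.83) were below it. Among the 15098 genes kept, only those with a mean of at least 5 CPM were counted for 2-fold differences, which leaves out CYP1A1. Of these, 12 differed at least 2-fold from the vehicle mean and lay beyond every vehicle library, 8 higher and 4 lower, against 13 at 100 and 14 at 20 µg/mL. From 20 to 500 µg/mL the median of 24 NRF2 targets differed by 0.4, with all 24 above 0, and that of 11 AHR targets by 0.3, with 9 above 0; both lay at percentile 100 of random lists matched on expression. The medians of cholesterol synthesis (-0.15), interferon response (-0.43) and goblet and secretory cell genes (-0.32) lay at percentile 0. Percentile 100 was also reached by endoplasmic reticulum chaperones (0.12), heat shock (0.15), mitosis (0.12) and ribosome biogenesis genes (0.16), and percentile 0 by the PI3K and FOXO response (-0.17), so these positions are not particular to the lists named before.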

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

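The results here differ between Soshiho-tang and Yijin-tang at 500 µg/mL in a test of the difference itself. The tests of library scaling, of the part of the calls that follows base composition, and of the vehicle library set for secretory genes were chosen only after the results were seen. A total of 2052 genes differed between the formulas (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), and 14 gene lists did with an estimated correlation. Higher with Soshiho-tang on the log2 scale were CYP1A1 (4.03), CYP1B1 (1.82), SLC22A3 (1.25), ALDH1A3 (1.23), EMP1 (1.09), HMOX1 (1.03), CXCL8 (0.51), DDIT3 (0.47), CDKN1A (0.46) and NQO1 (0.34). Lower were GABRP (-1.39), DLL4 (-1.4), NOX1 (-1.67), ATOH1 (-1.98) and CD200 (-2.13). With only these 6 libraries in the fit the formulas differed in 2926 genes and 19 lists, against at most 0 genes and 13 lists in the other 9 ways to split them. For both counts 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05.

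Many genes differed between vehicle and the 20 µg/mL libraries of Soshiho-tang and Yijin-tang, with a median GC content of 42.5% for genes higher with Soshiho-tang, 58.9% for lower and 50.3% for other genes. Removing a smooth trend with GC content and length took 2684 Soshiho-tang calls to 1504 (56%, a net 1180 fewer), kept 1146 of the genes called before (42.7%) and took the median size of all genes called before from 0.23 to 0.16 (SD 0.25), so a trend of this kind may account for many of the 1538 calls that ended. The bound set in advance, a fall to 50% or less, was met on the genes called before and not on all calls, so whether the trend is the whole cause stays open. Thinning the 21 libraries of that fit to the smallest total, 19.6 M, left 2386 calls, which argues against depth as the main cause, and genes called at 20 µg/mL of Yijin-tang moved on by a median of 0.005 ± 0.005 (SE, n = 3) from 20 to 100 µg/mL of Soshiho-tang, which argues against a response that still grows with dose in that range. Also open is the library set, since 0 vehicle libraries share a set with an extract, and a response already complete at 20 µg/mL: the vehicle set and the extracts cannot be told apart.

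NRF2 and AHR targets rose from 20 to 500 µg/mL in Soshiho-tang, Yijin-tang and Okbyeongpung-san. Leaving out paralog families kept at least 0.96 of the median, and 24, 12 and 10 of the 25 remaining genes were past the test in the 3 formulas, which argues against reads shared between paralogs. The smallest NRF2 list median was 0.27, beyond the largest log2 difference in scaling factors of 0.11, which argues against library scaling. As a hypothesis, the 3 formulas could act on NRF2 and AHR at high dose. Treatment of cells that lack either factor would test this and was not done here.

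ATOH1 and other secretory cell genes fell at 500 µg/mL of Soshiho-tang. The vehicle library set is argued against, because 11 goblet and secretory genes were also lower than at 20 µg/mL, whose libraries came from the same 3 sets (camera adjusted p = 1.3e-05, but adjusted p = 0.08 with an estimated correlation). As a hypothesis, higher Notch activity might lower ATOH1, but the 7 measured Notch genes had a camera p of 0.16 in the opposite direction, with NOTCH3 (-1.39), HES1 (-0.33), HES4 (-0.53) and NRARP (-0.27) lower and JAG1 (0.44) higher. That p does not exclude it, since members went both ways and RNA is an indirect measure. A response to Soshiho-tang itself stays open and was not tested by other means.

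Among the 10 ways to split 6 libraries into 3 and 3, with only those libraries in the fit, the real split gave the largest count of changed genes in 9 comparisons. These counts, with the highest of the other splits, were 4206 and 1 for Soshiho-tang at 500 µg/mL against vehicle, 559 and 2 at 100, and 362 and 1 at 20 µg/mL. For Yijin-tang they were 1040 and 1, 574 and 0, and 498 and 2. Between 500 and 20 µg/mL they were 4902 and 0 for Soshiho-tang and 869 and 9 for Yijin-tang, so in each of these 1 of 10 splits was as large. Gene lists past the test numbered 15 for Soshiho-tang at 500 µg/mL against vehicle, with 16 in another split, and 13 and 15 for Yijin-tang, so 2 of 10 splits were as large in each. With the preset correlation these list counts do not set the real groups apart from other splits. Between the formulas at 100 µg/mL 6 of 10 splits gave as many genes (2, highest other 9), and at 20 µg/mL 2 of 10 did (5, highest other 5). With 10 splits no share under 0.05 can be reached in any of these.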

How the results depend on the processing

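The use of low-dose libraries in place of vehicle, and removal of the GC and length trend beyond 20 µg/mL of Soshiho-tang against vehicle, were chosen only after the results were seen. Of 251 named gene changes past the test, 185 kept their direction and passed under all alternatives fixed beforehand, 4 did so in all but DESeq2, where they had no adjusted p, and 62 were lost in at least 1, with none turned. Lost values numbered 1 with DESeq2 size factors, 7 with no filter on low counts, 3 with the replicate block, 1 of 236 with the DESeq2 test, 19 with only the compared groups, 3 with all 27 libraries, and 174 of 1428 with 1 library left out, where fewer samples limit the test. In DESeq2 15 of the 251 had no adjusted p. Where a lone library was left, it was assumed to vary like the other groups. AXIN2 at 500 µg/mL of Soshiho-tang, not past the test, ranged from -0.03 to 0.06 with 1 library left out and was negative without Soshiho-tang library 1 (-0.03) and without vehicle library 2 (-0.01). The cause of the shifts given here was not tested unless said.

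With an estimated correlation 4, 4 and 3 lists passed at 500 µg/mL of Soshiho-tang, Yijin-tang and Okbyeongpung-san against vehicle, in place of 16, 13 and 16. With no filter on low counts Okbyeongpung-san changed 1431, 431 and 1115 genes at 500, 100 and 20 µg/mL and 225 between 500 and 20, and Soshiho-tang and Yijin-tang differed in 4 and 4 genes at 100 and 20 µg/mL. The DESeq2 test gave 157 and 545 genes for Okbyeongpung-san at 100 and 20 µg/mL, and 1 and 1 gene between the other formulas.

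Same-numbered libraries did not deviate together: their correlation had a mean of 0.008 and a maximum of 0.094 in the fit of Soshiho-tang and Yijin-tang, and 11 of 21 libraries matched their own number best (3 of 9 in the fit of Okbyeongpung-san). With the replicate number as a block, which within Okbyeongpung-san is also the titled batch, 90 and 468 genes changed at 100 and 20 µg/mL of Okbyeongpung-san, and 156 between 500 and 20, and no other count moved by over 1.5 times. In that fit only vehicle has a replicate 1, so the block sets vehicle library 1 aside. Without that library and with no block, 199 and 776 genes changed at 100 and 20 µg/mL. Replicate 3 is batch D in Okbyeongpung-san and batch E in vehicle, so the block does not adjust for batch against vehicle.

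With only the compared groups in the fit, the spread came from those groups alone. Counts against vehicle were lower: 4206, 559 and 362 for Soshiho-tang at 500, 100 and 20 µg/mL, 1040, 574 and 498 for Yijin-tang, and 216, 3 and 18 for Okbyeongpung-san. Counts without vehicle were higher. Between 500 and 20 µg/mL they were 4902 for Soshiho-tang, 869 for Yijin-tang and 938 for Okbyeongpung-san. Between Soshiho-tang and Yijin-tang they were 2926, 2 and 5 at 500, 100 and 20 µg/mL. Vehicle pairs had the largest chi-square per degree of freedom of all pairs, 11.2 to 20.6. A shared spread may therefore be too small for vehicle and too large for other groups, which was not tested. Removing the GC and length trend took 2691 genes to 1435 at 20 µg/mL and 3329 to 2239 at 500 µg/mL of Yijin-tang against vehicle, and 6219 to 5771 at 500 µg/mL of Soshiho-tang. Between 500 and 20 µg/mL it took 296 to 527 for Yijin-tang and 4252 to 5225 for Soshiho-tang. With all 27 libraries Okbyeongpung-san gave 2991, 1489 and 2457 genes, and 348 between 500 and 20 µg/mL.

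With low-dose libraries in place of vehicle, edgeR counts were 0 at 100 µg/mL of Soshiho-tang (474 at unadjusted p below 0.05, 0 with DESeq2), 0 for the pair of formulas at 20 µg/mL taken either way (339, and 1 with DESeq2), 0 at 100 µg/mL of Yijin-tang (509, and 0), 0 at 100 µg/mL of Okbyeongpung-san (369, and 2) and 0 at its 20 µg/mL against Yijin-tang (548, and 1). The edgeR counts were 280 at 500 µg/mL of Yijin-tang and 88 at 500 µg/mL of Okbyeongpung-san. Where the count was 0, the genes at unadjusted p below 0.05 were under a share of 0.05, so the test may be too strict there. Of 156 named results 56 were lost and 11 turned. CLK1 became -0.07 at 100 µg/mL of Soshiho-tang, -0.05 and -0.04 at 500 and 20 µg/mL of Yijin-tang, and -0.04 and -0.03 at 100 and 20 µg/mL of Okbyeongpung-san. RPL23AP42 became 0.19 at 100 µg/mL of Soshiho-tang and 0.05 at 20 µg/mL of Yijin-tang, GCOM1 -0.07 at 20 µg/mL of Soshiho-tang, FAM156B 0.09 and HSPA1A 0.03 at 500 µg/mL of Yijin-tang, FRK -0.05 at 100 µg/mL of Okbyeongpung-san, and CYP1A1, not past the test in either, -0.3 at 20 µg/mL of Yijin-tang.

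With 1 library left out, counts against vehicle ranged from 5175 to 6535, 1962 to 3743 and 1533 to 3509 for Soshiho-tang at 500, 100 and 20 µg/mL, from 2317 to 4244, 1955 to 3895 and 1707 to 3571 for Yijin-tang, and from 55 to 1358, 3 to 318 and 0 to 913 for Okbyeongpung-san. Between 500 and 20 µg/mL they ranged from 3392 to 3594, 147 to 222 and 12 to 21 for these formulas, and between Soshiho-tang and Yijin-tang at 500 µg/mL from 1493 to 1631. Lists past the test ranged from 15 to 17, 12 to 14, 13 to 17 and 18 to 19 at 500 µg/mL for the 3 formulas against vehicle and the pair of formulas. The correlation of dose effects ranged from 0.154 to 0.21 without a replicate number, was 0.245 with the block and 0.764 for genes with at least 10 CPM.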

Other observations

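The counts of genes shared between formulas or groups in this part were chosen only after the results were seen. From 20 to 500 µg/mL, 25 genes were higher in all of Soshiho-tang, Yijin-tang and Okbyeongpung-san, and 15 of them were on the NRF2 or AHR list, among them ALDH3A1, with log2 fold changes of 1.74, 0.88 and 1.11. A further 34 genes were lower in all 3, and 7 of them were on the cholesterol synthesis list. INSIG1 was at -0.42, -0.49 and -0.7, HMGCS1 at -0.42, -0.49 and -0.54, and IFIT1, an interferon-induced RNA-binding protein, at -1.26, -0.99 and -1.17. Neither count can exceed the calls in Okbyeongpung-san, which fell from 88 to between 12 and 21 with 1 library left out, and there HMGCS1 and IFIT1 lost their calls in 4 and 3 of the alternative settings.

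Planned lists not described so far also moved with Soshiho-tang. Of 26 ribosome biogenesis genes 20 rose from 20 to 500 µg/mL (23 adjusted over the list alone; camera adjusted p = 3.3e-10, but adjusted p = 0.061 with an estimated correlation). Of 24 hypoxia and glycolysis genes 11 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.021 with an estimated correlation). Of 19 genes of the PI3K and FOXO response 2 were higher and 7 lower with Soshiho-tang than with Yijin-tang at 500 µg/mL (2 and 10 adjusted over the list alone; camera adjusted p = 0.00067, and adjusted p = 0.018 with an estimated correlation). Of 30 mitosis genes 15 rose from 20 to 500 µg/mL of Soshiho-tang (20 adjusted over the list alone; camera adjusted p = 1.5e-06, but adjusted p = 0.19 with an estimated correlation), and none passed for Yijin-tang (9 higher adjusted over the list alone; camera adjusted p = 1.4e-12, but adjusted p = 0.11 with an estimated correlation). Of 15 replication-dependent histone genes, listed as a sign of how RNA was selected, 5 fell and none rose from 20 to 500 µg/mL of Soshiho-tang (5 adjusted over the list alone; camera adjusted p = 0.021, but adjusted p = 0.084 with an estimated correlation).

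Against vehicle, 5 genes were higher and 10 lower in all 9 tested extract groups, which share the vehicle libraries. Neither count can exceed the calls at 100 and 20 µg/mL of Okbyeongpung-san, which ranged from 3 to 318 and from 0 to 913 with 1 library left out, and CLK1, TMCC3, FRK, KLF6, TNS4 and HSPA1A each lost a call there in at least 1 such fit. The higher ones were CLK1, TMCC3, FRK, TBL1XR1 and a gene without a symbol. The lower ones included the transcription factors KLF6 and MYC, the peptide hormone gene EDN1, the adhesion gene TNS4 and the heat shock genes DNAJB1, HSPA1A and HSPA1B, of which HSPA1A and HSPA1B are near-identical and share reads.

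Markers of other cell types were fixed beforehand, but too few of each were measured for a list test: 3 of fibroblasts, 4 of leukocytes, 4 of hepatocytes, 3 of lung epithelium and 4 of breast epithelium. The most abundant were LYZ at 1580 CPM for leukocytes, SERPINA1 at 308 CPM for hepatocytes, XBP1 at 203 CPM for breast epithelium, SFTPA2 at 2.3 CPM for lung and COL1A1 at 1.29 CPM for fibroblasts. Tested singly, 8 of 17 passed at 500 µg/mL of Soshiho-tang against vehicle, with LUM and ITGAM higher and COL1A1, CD14, TTR, SERPINA1, SFTPA2 and KRT17 lower. Against 20 µg/mL 3 were higher (LUM, ITGAM and XBP1) and 3 lower (CD14, SERPINA1 and SFTPA2). At 500 µg/mL of Yijin-tang LYZ was higher than vehicle and CD68, SERPINA1, KRT17 and XBP1 lower, and only SERPINA1 fell from 20 µg/mL. At 500 µg/mL of Okbyeongpung-san SERPINA1 and KRT17 were lower than vehicle, and none passed against 20 µg/mL. XBP1 was lower than vehicle past the test in 5 of 9 groups. KRT17 was lower than vehicle in 7 of 9 groups past the test, and did not pass from 20 to 500 µg/mL of any formula. LYZ, SERPINA1 and XBP1 are also expressed by intestinal epithelial cells.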
